A study of Mus musculus with 20 samples.

How the data were processed

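The series profiled LLC-1 tumors, implants of a Lewis lung carcinoma cell line, grown in C57Bl/6 mice and injected with adenoviral vectors. Per the labels, each injection held 25 µl of buffer with a viral load of 8 on the log10 scale of infectious units, and 5 injections were given 48 h apart. Each of 4 groups had 5 arrays. The vectors carried enhanced green fluorescent protein (eGFP, the control), IFNbeta, p19Arf, or p19Arf together with IFNbeta. Total RNA was extracted with Trizol and labelled with biotin for 1-colour Affymetrix arrays, per the labels' protocols.

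The values used were 1 deposited table of 35556 probe sets by 20 arrays. Its values ran from 2.33 to 14.7 and the array medians from 7.49 to 7.61, so they were taken as log2 expression values that the authors had already summarised and normalized. The base of the logarithm was read from this range and not from a header. Affymetrix Expression Console and GCOS are named in the submitters' processing notes, without versions. The summarisation method, the background correction and any filter are not given in the sources used here. No step of background correction or normalization was added, since the deposited values already had array medians within a narrow range. The number of arrays limits the precision, and the table carries no detection call or background estimate per probe set.

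Probe sets were named through the platform annotation, with symbols updated by gene identifier to the mouse gene table of assembly GRCm38.p6, from which only names were used. Exactly 1 symbol was paired with 21789 probe sets and several with 1621, and 12146 probe sets were not listed in the annotation table and are unnamed here. For 91 probe sets the gene identifier had no match and the annotation's own symbol was kept. Only probe sets with 1 symbol were used, and of several for a gene the one with the highest mean over all 20 arrays, which gave 19938 genes with no filter on low values. Among the 999 genes with several probe sets, the median correlation of 2 probe sets of a gene across arrays was 0.664, so probe sets of 1 gene did not always move together. Genes of near-identical families, such as Ifit3b, the Ifi200 family and the olfactory receptors, can share probe sequence with their relatives, and their values are uncertain to that extent.

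Genes were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 20 arrays, which left 16 residual degrees of freedom, and the variances were moderated with eBayes (prior degrees of freedom 6.06). All tests were 2-sided. The 7 contrasts were each vector group against eGFP, the combination against each single vector, IFNbeta against p19Arf, and the interaction. The interaction is the difference between the combination and IFNbeta minus the difference between p19Arf and eGFP, on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method within each contrast and a gene passed at an adjusted p under 0.05. The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

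The 28 gene lists covered the type I interferon response, interferon gamma associated genes, MHC class I and peptide loading, MHC class II, p53 targets, cell cycle, cell death effectors, and ER stress and the unfolded protein response. They also covered chemokines, NF-kB and inflammatory cytokines, T cell markers, NK cell markers, cytotoxic effectors, immune checkpoints and regulatory T cells, B and plasma cell markers, macrophage and monocyte markers, neutrophil markers, dendritic cell markers, and mast cell and eosinophil markers. The others were endothelial markers, fibroblast and matrix genes, skin epidermis markers, hair follicle keratins, skeletal muscle markers, adipocyte markers, erythroid and platelet markers, hypoxia and glycolysis, and the mitochondrial respiratory chain. Of 507 members written, 469 were measured, 8 to 31 per list. A few genes stood in more than 1 list. Each list was tested with fry, limma's rotation test, which asks whether its genes move on balance in 1 direction. A second p from fry asks whether they change in either direction, and neither p compares the list with other genes. Adjustment was over the 28 lists within a contrast. The list score was the mean log2 value of the measured members on each array, with its difference, standard error (SE) and 95% confidence interval from the same linear model. Camera was run with its preset correlation of 0.01 and with an estimated correlation. It asks whether a list shifts in 1 direction relative to other genes, so it does not test change in either direction. The list scores were also compared by an exact 2-sided permutation test, whose smallest possible p with 5 arrays against 5 is 0.00794.

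The named genes of a contrast were the vector genes Cdkn2a and Ifnb1 and, of the genes that passed, the 8 with the largest positive and the 8 with the largest negative difference, leaving out predicted or unnamed genes and immunoglobulin or T cell receptor segments. For each list that passed, or that had a member past the threshold over all genes, up to 4 members with the smallest unadjusted p were named. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were named, or 4 in the 2 contrasts where the fifth was a predicted or unnamed gene, and are said not to have passed. The text also names members of lists that did not pass, taken among those with the smallest unadjusted p in the list; these were chosen after their values were seen.

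The tests were checked on simulated data, made from shuffled residuals of the real arrays, in 20 runs over 19938 genes. In each run 100 genes were changed by each fold size, raised and lowered in alternation. In the IFNbeta versus eGFP simulation 96.8% of genes changed 2-fold and 69% of genes changed 1.5-fold were found, with a median of 1.5 wrong calls and at most 75. For p19Arf versus eGFP the shares were 97.1% and 69.4%, with a median of 0 wrong calls but 2985 in the run with the most. For p19Arf+IFNbeta versus eGFP they were 96.4% and 69.4%, with a median of 1 and at most 11. These shares hold for 200 changed genes in a run. With fewer, the Benjamini-Hochberg method asks for smaller p-values, and that case was not simulated. A count of 0 therefore does not show that no gene changed 2-fold. In the simulations of a list of 29 members among 28 lists, a shift of 0.5 passed in 11, 12 and 10 of 20 runs for these 3 contrasts and a shift of 1 in 20 of 20 for each, while a shift of 0 passed in 0.

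Alternatives fixed beforehand were quantile normalization, centring each array on its median, leaving out the lowest 25% of genes by mean, testing every probe set, averaging the probe sets of a gene, trended and robust moderation, array weights, fitting only the 2 groups compared, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the spread of each array as a covariate, leaving out the 5 arrays of lowest spread, the fry p in either direction, and the covariate without the array of IFNbeta replicate 3. Comparisons that share the eGFP arrays were set beside 100 simulations of unchanged groups and were repeated with the eGFP arrays split into 2 and 3. The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.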

Results

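Gene expression was measured on 20 arrays of implanted LLC-1 tumors, 5 for each vector: eGFP as the control, IFNbeta, p19Arf, and p19Arf with IFNbeta. Interferon beta is a secreted antiviral cytokine, and p19Arf is a tumor suppressor protein, encoded by an alternative reading frame of Cdkn2a, that stabilises p53 by binding Mdm2. Correlations between arrays of 1 group ran from 0.951 to 0.994, and the highest between arrays of different groups was 0.995. At most 0.0366% of probe sets held equal values on any 2 arrays, so no array was a copy of another. The first principal component held 46.4% of the variance, the second 17.1% and the third 5.57%. The standard deviation of the log2 values on an array, called its spread here, ran from 1.99 to 2.15. Its group means were 2.11 ± 0.03 for eGFP, 2.11 ± 0.04 for IFNbeta, 2.06 ± 0.05 for p19Arf and 2.06 ± 0.05 for the combination (SD, n = 5 each).

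Transcripts of the tissues around a tumor varied between arrays of every group. The skeletal muscle list, contractile and metabolic genes of muscle fibres, had a mean score of 7.64 ± 0.27 in eGFP, 8.43 ± 0.76 in IFNbeta, 8.12 ± 0.64 in p19Arf and 8.41 ± 0.62 in the combination (SD, n = 5 each). Of its 18 members, 18, 17 and 17 had a higher mean than eGFP in IFNbeta, p19Arf and the combination, with score differences of 0.79 (SE 0.38), 0.48 and 0.77. The first was 0.53 without IFNbeta replicate 4 and the second 0.29 without p19Arf replicate 2. The fry adjusted p-values were 0.416, 0.999 and 0.238. The array of IFNbeta replicate 3 had a skin epidermis score of 8.69, against 6.51 to 6.64 on the other 4 arrays of its group. The mean level of 51 small nucleolar RNA genes, which guide the chemical modification of ribosomal RNA, was 9.39 in eGFP, 9.43 in IFNbeta, 9.81 in p19Arf and 9.75 in the combination. Across the 20 arrays this level was lower where the spread was higher (Pearson r = -0.762, permutation p = 0.00016, Spearman rho = -0.696, permutation p = 0.00079). Without the 2 arrays farthest from the median spread r was -0.763, and for deviations from the group means it was -0.691. It was 1 of 5 relations computed, with Benjamini-Hochberg values of 4e-04 and 0.00193.

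Scores of some gene lists followed the spread across the 20 arrays. Hypoxia and glycolysis, another of the 5 relations, gave r = 0.659 (permutation p = 0.0018, adjusted 0.003; Spearman 0.69, permutation p = 0.00116, adjusted 0.00193), 0.657 without the 2 arrays farthest from the median spread and 0.504 for deviations from the group means. Among 9 lists of host cells, macrophage and monocyte markers gave r = 0.87 (Spearman 0.859, both permutation p-values 1e-05, adjusted 9e-05), 0.871 without the 2 arrays and 0.851 for deviations from the group means. Endothelial markers gave r = 0.591 (permutation p = 0.00559, adjusted 0.0252; Spearman 0.63, permutation p = 0.00356, adjusted 0.016), 0.645 without the 2 arrays and 0.556 for the deviations. Genes of high level move with the spread in part by its definition. Of 1000 random lists of matched level 958, 549 and 324 had an r as high as these 3 lists. After quantile normalization the random lists still had median r-values of 0.639, 0.542 and 0.124 with the spread. Its definition is thus not the whole source of the relation. The 3 lists then gave r = -0.059, 0.784 and 0.515, with 801, 189 and 276 random lists as high.

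**Figure D1:**
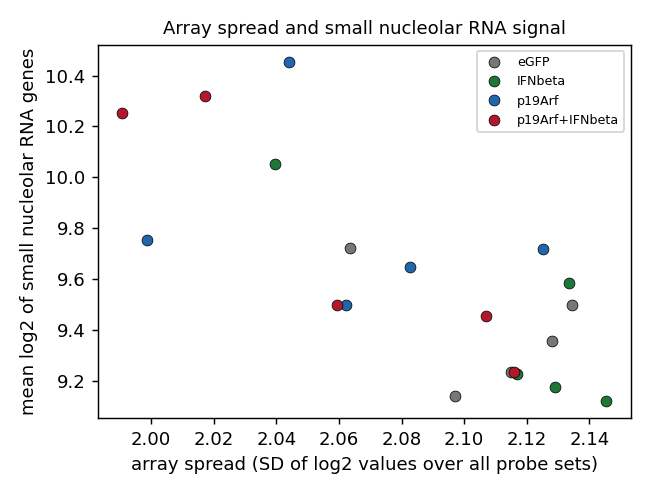
Array spread (horizontal axis, the standard deviation of log2 values over all probe sets) against the mean log2 level of 51 small nucleolar RNA genes (vertical axis), with 1 point per array coloured by vector group. Arrays of lower spread had the higher small nucleolar RNA level, with a Pearson r of -0.762 over 20 arrays.

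The transcripts of the genes carried by the vectors were examined at their array probe sets. Cdkn2a was at 7.43 ± 0.07 in eGFP, 7.38 ± 0.09 in IFNbeta, 7.58 ± 0.19 in p19Arf and 7.55 ± 0.21 in p19Arf+IFNbeta (SD, n = 5 each). The differences from eGFP were -0.06, 0.14 and 0.12 on the log2 scale (SE 0.10 each), with exact permutation p-values of 0.294, 0.159 and 0.294. With the array spread as a covariate the last 2 were 0.04 and 0.003, and without replicate 4 of p19Arf or of the combination they were 0.09 and 0.05. The first was -0.12 with array weights and -0.03 without eGFP replicate 3. Ifnb1 was at 6.10 ± 0.14 in eGFP, 6.21 ± 0.26 in IFNbeta, 6.00 ± 0.23 in p19Arf and 6.03 ± 0.23 in the combination, with differences of 0.10, -0.11 and -0.08 (SE 0.13 each). The exact permutation p-values were 0.516, 0.437 and 0.508. The Ifnb1 difference of IFNbeta from eGFP was -0.01 without IFNbeta replicate 3, the array with the highest value, that of p19Arf was -0.01 without p19Arf replicate 2, and that of the combination -0.02 without its replicate 5 and -0.17 with the array spread as a covariate. Each gene had 1 probe set, at the 43.2 and 15.9 percentile of mean level among all genes. The position of these probe sets relative to the vector inserts is not given in the sources used here, and a probe outside the insert would check nothing, so the group labels could be neither backed nor questioned from them.

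The comparison of IFNbeta with eGFP concerned what the interferon vector changed relative to the control vector. Genes of the type I interferon response, the antiviral program switched on through the interferon alpha and beta receptor, had higher means in the IFNbeta tumors for all 29 of 29 measured members. The list score was 9.98 ± 0.28 against 9.58 ± 0.05 in eGFP (SD, n = 5 each), a difference of 0.40 (SE 0.13, 95% interval 0.13 to 0.67), and each of the 5 IFNbeta arrays lay above all 5 eGFP arrays. Usp18, a protease that removes ISG15 from proteins, differed by 0.59, Ifi27l2a by 0.56, Cmpk2, a mitochondrial nucleotide kinase, by 0.51, Oas1a, which makes the activator of RNase L, by 0.46, Trim30a by 0.42 and Rtp4 by 0.36. Gzmb, the granzyme of cytotoxic lymphocytes, was at 9.57 ± 0.32 against 8.88 ± 0.21. Of the interferon list 0 members passed over all genes and 22 did when adjusted over the list alone. The fry adjusted p of the list was 0.172, and with an estimated correlation in camera p = 0.00254 (adjusted p = 0.0667). The exact permutation p of the list score was 0.00794, the smallest possible (adjusted p = 0.0741).

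**Figure D2:**
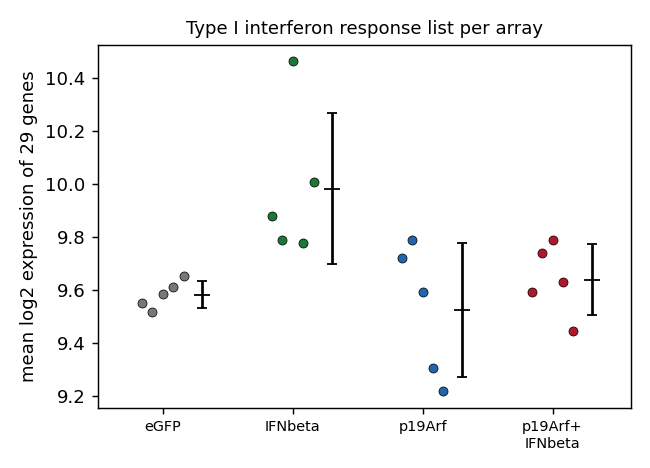
Mean log2 expression of the 29 measured type I interferon response genes (vertical axis) on each array, by vector group; points are arrays and the bar beside them is the mean with its SD, n = 5. The IFNbeta arrays had a mean of 9.98, with 1 array at 10.46, against 9.58 in eGFP, 9.52 in p19Arf and 9.64 in the combination.

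No single gene passed in IFNbeta against eGFP: limma gave 0 genes at an adjusted p under 0.05, with the smallest at 0.836, and 557 at an unadjusted p under 0.05 (268 higher, 289 lower), where chance gives about 997 of 19938. Trended and robust moderation also gave 0, array weights gave 5 and leaving out the 5 arrays of lowest spread gave 1. The 5 genes with the smallest unadjusted p did not pass, with an adjusted p of 0.836 for the smallest and close to 1 for the other 4, although in each all 5 IFNbeta arrays lay beyond all 5 eGFP arrays. They were Ms4a4d, a membrane protein of the MS4A family, at 0.79 (SE 0.15), Fcrl5, an Fc receptor-like protein of B cells, at 0.66 (SE 0.14), Phf11d at 0.73 (SE 0.16), Ifit3b, an interferon-induced tetratricopeptide protein, at 0.83 (SE 0.19), and Dbp, a clock-controlled transcription factor, at -0.52 (SE 0.12).

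Other lists compared between IFNbeta and eGFP tumors did not pass by the directional test either. Of the p53 target genes, 23 of 27 had higher means than in eGFP, with a score difference of 0.16 (SE 0.05) and an exact permutation p of 0.00794. Mdm2, the ligase that degrades p53, differed by 0.32, Zmat3 by 0.27 and Eda2r by 0.44, while 0 members passed over all genes or adjusted over the list alone. The fry adjusted p was 0.172, and with an estimated correlation the list did not pass either (p = 0.00476, adjusted 0.0667). With array weights it passed by fry at an adjusted p of 0.0228, within a range of 2.5e-09 to 0.628 over its alternatives. Of the genes of ER stress and the unfolded protein response, 16 of 17 had higher means (score difference 0.14, fry adjusted p 0.271, p = 0.0089 with an estimated correlation, adjusted 0.0831), with Trib3 at 0.34 and Atf3 at 0.39. The cytotoxic effector score differed by 0.26 (SE 0.13, fry adjusted p 0.448) with 9 of 10 members higher, the NK cell score by 0.09 (SE 0.07, 0.612) and the T cell score by 0.14 (SE 0.11, 0.612). Adipocyte markers, among them Fabp4 at 0.69, differed by 0.27 (SE 0.18, 10 of 12 higher, 0.612). The hair follicle keratin list had 0 of 14 members higher, with a difference of -0.19 (SE 0.11, 0.473). Without IFNbeta replicate 5 the T cell difference was 0.07, without eGFP replicate 2 or IFNbeta replicate 1 the adipocyte difference was 0.16 or 0.17, and without eGFP replicate 5 the hair follicle difference was -0.10.

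The comparison of p19Arf with eGFP concerned the tumor suppressor vector on its own. Endothelial markers had lower means in 15 of 17 genes in the p19Arf tumors, with a score difference of -0.16 (SE 0.05) that was -0.11 with the array spread, which this score followed at r = 0.591, as a covariate. Cdh5, the cadherin of endothelial junctions, was at 9.27 ± 0.33 against 9.85 ± 0.25 in eGFP and Emcn, a sialomucin of veins and capillaries, at 7.98 ± 0.39 against 8.52 ± 0.33 (SD, n = 5 each). Cpa3, the carboxypeptidase of mast cell granules, was at 7.88 ± 0.41 against 8.95 ± 0.38. Chemokine genes had lower means in 20 of 24 members, among them Ccl17 at -0.56, Ccl12 at -0.60 and Cxcl10 at -0.45. The p53 target list differed by 0.03 (SE 0.05, 16 of 27 higher) and by -0.01 after median centring, with Zmat3 at 0.26 and Mdm2 at 0.17.

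In that comparison limma gave 0 genes past the threshold, with a smallest adjusted p of 0.661, and 1445 at an unadjusted p under 0.05 (567 higher, 878 lower); array weights and trended, robust moderation also gave 0. The 5 genes with the smallest unadjusted p had an adjusted p of 0.661 each and did not pass. They were the olfactory receptor genes Olfr1300-ps1 at 0.56, Olfr594 at 0.50 and Olfr1215 at 0.47, Cpa3 at -1.07 (SE 0.26), and Rfk, the riboflavin kinase, at -0.63 (SE 0.16). With the array spread as a covariate the Rfk difference was -0.38, and with array weights that of Olfr1300-ps1 was 0.37. The mean of all 1027 olfactory receptor genes, which lie at low levels, ran from 5.29 to 5.94 on the p19Arf arrays against 5.25 to 5.42 on the eGFP arrays, and p19Arf replicate 4, where it was 5.94, was also the highest array in each of these 3 genes. In Olfr594 4 of the 5 p19Arf arrays lay beyond all eGFP arrays and in the others 5 did. The endothelial list had a fry adjusted p of 0.347, 0 members past over all genes and 1, Cdh5, adjusted over the list alone (p = 0.0355 with an estimated correlation, exact permutation p = 0.0238), and its difference was -0.10 with array weights. The chemokine list score differed by -0.15 (SE 0.07, fry adjusted p 0.738, 0 members adjusted over the list alone). Adjusted over the list alone, Cpa3 also passed among mast cell and eosinophil markers (score difference -0.08, median member difference 0.01, fry adjusted p 0.999) and Gzmc, at -0.68, among cytotoxic effectors. The type I interferon list differed by -0.06 (SE 0.13, 21 of 29 lower, 0.999) and its sign turned under quantile normalization. The cell cycle list, which followed the array spread (r = 0.938), differed by -0.13 (SE 0.14, 27 of 31 lower, 0.999), or -0.07 under quantile normalization.

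The combination of p19Arf and IFNbeta against eGFP concerned both vectors together. Chemokine genes stood on both sides of the control. Ccl3, a macrophage inflammatory protein, was at 11.72 ± 0.59 against 10.77 ± 0.24 in eGFP and Cxcl3, a neutrophil attractant, at 8.72 ± 0.47 against 8.05 ± 0.18 (SD, n = 5 each). Ccl17 and Ccl22, which attract CCR4-bearing T cells, were at 7.49 ± 0.08 against 8.20 ± 0.22 and at 7.69 ± 0.15 against 8.16 ± 0.10. Ccl8 was at 10.46 ± 0.25 against 11.01 ± 0.19 and Ccl12 at 7.89 ± 0.31 against 8.62 ± 0.50. Fibrillar collagen was higher in mean, with Col1a1 at 12.06 ± 0.46 against 10.68 ± 0.88.

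**Figure D3:**
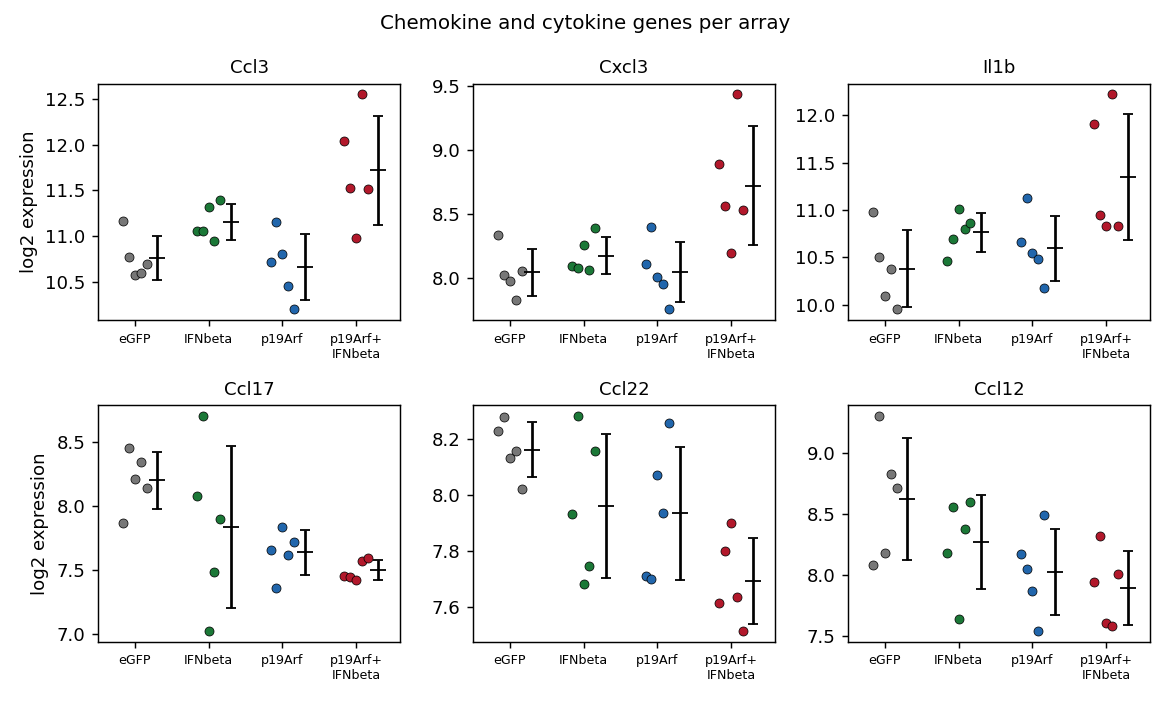
Log2 expression (vertical axes) of Ccl3, Cxcl3, Il1b, Ccl17, Ccl22 and Ccl12 on each array, by vector group; points are arrays and the bar beside them is the mean with its SD, n = 5. Ccl3, Cxcl3 and Il1b had their highest group means in the combination (11.72, 8.72 and 11.35) and Ccl17, Ccl22 and Ccl12 their lowest (7.49, 7.69 and 7.89).

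For the combination against eGFP limma gave 0 genes past the threshold, with a smallest adjusted p of 0.234, and 3513 at an unadjusted p under 0.05 (1233 higher, 2280 lower). Trended and robust moderation also gave 0. Array weights gave 166, leaving out the 5 arrays of lowest spread gave 3, and leaving out eGFP replicate 1 gave 84 (40 higher, 44 lower). The 4 genes with the smallest unadjusted p did not pass, at an adjusted p of 0.234 each. They were Mfap4, a microfibril-associated protein, at 0.77 (SE 0.14), the microRNA gene Mir369 at 0.47, the zinc finger gene Zfp930 at -0.68, and Dbp at -0.58. In Dbp 3 of 5 arrays lay beyond all eGFP arrays and in the other 3 genes 5 did.

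By the directional fry test 0 of the 28 lists passed in the combination against eGFP, with a smallest adjusted p of 0.207. By the fry p in either direction, which was added after lists with members on both sides had been seen, 6 passed. That p was not recomputed under the alternative settings or with arrays left out. Values given under those settings are score differences. The chemokine list changed in either direction (adjusted p = 0.00601), with 0 of 24 members past over all genes and 8 adjusted over the list alone. In camera with an estimated correlation, a test of 1 direction, its adjusted p was 0.959. Its score difference was -0.02 (SE 0.07, directional adjusted p 0.872), or 0.04 under quantile normalization. In the fibroblast and matrix list (0.0128 in either direction, 0.207 directional) 14 of 18 members were higher and 11 passed adjusted over the list alone. Its score difference was 0.28 (SE 0.11; p = 0.0694 with an estimated correlation, adjusted 0.624), or 0.42 without the 5 arrays of lowest spread, with Col1a1 at 1.38, Col1a2 at 1.29, Mfap5 at 0.80 and Fn1, fibronectin, at -0.41. In the hypoxia and glycolysis list (0.0128 and 0.207) 12 of 18 members were lower and 7 passed adjusted over the list alone, with a score difference of -0.14 (SE 0.05, exact permutation p = 0.0159). That difference was -0.04 under quantile normalization and -0.09 with the array spread, which this score followed at r = 0.659, as a covariate, and with an estimated correlation p was 0.115 (adjusted 0.624). Ndrg1 was at -0.50, Egln3, a prolyl hydroxylase acting on hypoxia-inducible factor, at -0.48, Pdk1 at -0.32 and Pfkfb3, an activator of glycolysis, at 0.38.

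The remaining lists that passed in either direction were of myeloid cells and inflammation. Among neutrophil markers (0.0246 in either direction, 0.207 directional) 13 of 17 were higher and 4 passed adjusted over the list alone, with a score difference of 0.18 (SE 0.11; p = 0.0709 with an estimated correlation, adjusted 0.624), or 0.10 without p19Arf+IFNbeta replicate 1. S100a9, a subunit of calprotectin, was at 0.69 and Csf3r, the receptor for G-CSF, at 0.61, but Mmp9 at -1.12. Among dendritic cell markers (0.0246 and 0.238) 9 of 14 were lower, with a score difference of -0.10 (SE 0.04; p = 0.145 with an estimated correlation, adjusted 0.624), Fscn1 at -0.50 and Ccr7, which guides dendritic cells to lymph nodes, at -0.32, and 2 passed adjusted over the list alone. In the NF-kB and inflammatory cytokine list (0.0467 and 0.207) 16 of 17 were higher and 4 passed adjusted over the list alone, with a score difference of 0.29 (SE 0.11; p = 0.0812 with an estimated correlation, adjusted 0.624). Il1b was at 11.35 ± 0.67 against 10.38 ± 0.40 (SD, n = 5 each), Osm differed by 0.59 and Nfkbiz by 0.49. Of the 6 lists 0 had a member past the threshold over all genes.

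The other lists did not pass by either test in the combination against eGFP. Among T cell markers, 3 of 16 passed adjusted over the list alone, with Cd8b1 at 0.70, Cd8a at 0.56 and Cd3d at 0.45 and a score difference of 0.22 (SE 0.11, fry adjusted p 0.238), or 0.11 without p19Arf+IFNbeta replicate 1. Interferon gamma associated genes differed by 0.18 (SE 0.10, 0.238), with Gbp5, a guanylate-binding protein, at 0.46, Gbp4 at 0.44 and Irf1 at 0.33 as the 3 members passing adjusted over the list alone. MHC class I and peptide loading genes differed by 0.12 (SE 0.07, 0.410), or 0.23 under quantile normalization and 0.08 after median centring, with 3 passing in that way: Nlrc5, the transactivator of class I genes, at 0.68, and the peptide transporter genes Tap1 at 0.41 and Tap2 at 0.34. MHC class II genes differed by 0.05 (SE 0.12, 0.872), or 0.11 under quantile normalization and 0.008 after median centring. Cytotoxic effectors differed by 0.16 (SE 0.13, 0.503), or 0.02 without p19Arf+IFNbeta replicate 1 and 0.26 without replicate 5. NK cell markers differed by 0.05 (0.727), or 0.02 after median centring, and B and plasma cell markers by -0.04 (SE 0.21, 0.874). Immune checkpoints and regulatory T cell genes differed by 0.15 (SE 0.08, 0.305), with Cd274, the ligand of PD-1, at 0.59. Macrophage and monocyte markers differed by -0.15 (SE 0.12, 0.394), with Folr2 at -0.61, Mrc1 at -0.52 and Cd163 at -0.44. This score, which followed the array spread at r = 0.87, differed by -0.06 without p19Arf+IFNbeta replicate 4, the array of lowest spread, by -0.09 without replicate 5, by -0.22 without replicate 2 and by -0.08 under quantile normalization. Mast cell and eosinophil markers differed by -0.12 (SE 0.05, 0.238), with Cpa3 at -0.97, Fcer1a at -0.42, Mcpt4 at -0.45 and Hdc at 0.67.

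The lists of cell programs and of surrounding tissues did not pass in the combination against eGFP either. The cell cycle score differed by -0.25 (SE 0.14, 28 of 31 lower, fry adjusted p 0.327), or -0.17 under quantile normalization. The p53 target score differed by 0.05 (SE 0.05, 18 of 27 higher, 0.364) with Btg2 at 0.53 and Fas at 0.47, and was 0.09 under quantile normalization and 0.01 after median centring. The type I interferon score differed by 0.06 (SE 0.13, 16 of 29 higher, 0.872), or 0.14 under quantile normalization and 0.02 after median centring. Cell death effectors differed by -0.02 (0.872) and ER stress genes by -0.05 (0.874), and both signs turned under quantile normalization. The mitochondrial respiratory chain score differed by -0.17 (SE 0.12, 0.394), or -0.07 under quantile normalization, and followed the array spread at r = 0.858 (permutation p = 1e-05, adjusted over 28 lists 7e-05; Spearman 0.835, permutation p = 2e-05, adjusted 0.00014), 0.901 without the 2 arrays farthest from the median spread. Of 1000 random lists of matched level 923 had an r as high, so this relation is one of expression level. Without p19Arf+IFNbeta replicate 4 the cell cycle difference was -0.14 and the respiratory chain difference -0.08. Endothelial markers differed by -0.02 (SE 0.05, 0.986, median member difference 0.01), skin epidermis markers by -0.12 (SE 0.32, 0.872; -0.0026 without eGFP replicate 5), adipocyte markers by 0.06 (SE 0.18, 0.872; 0.02 after median centring), and erythroid and platelet markers by -0.04 (SE 0.08, 0.872). The hair follicle keratin score was 7.05 in the combination and 7.04 in eGFP (0.986), with a median member difference of -0.02, and the sign of the mean difference turned under quantile normalization and median centring.

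The combination against IFNbeta alone compared tumors given both vectors with tumors given the interferon vector. The labels give the same viral load for every group and no separate load per vector. A lower dose of the IFNbeta vector in the combination therefore cannot be told apart from an effect of p19Arf. Genes of the type I interferon list had lower means in the combination than in IFNbeta in 28 of 29 members. The list score was 9.64 ± 0.13 against 9.98 ± 0.28 (SD, n = 5 each), a difference of -0.34 (SE 0.13, 95% interval -0.61 to -0.07), with 4 of 5 combination arrays below all IFNbeta arrays; it was -0.22 without IFNbeta replicate 3 and -0.16 without the 5 arrays of lowest spread. Cmpk2 was at 8.66 ± 0.30 against 9.47 ± 0.22 and Samd9l, an interferon-inducible antiviral restriction factor, at 9.98 ± 0.17 against 10.54 ± 0.08, while Usp18 differed by -0.77, Ifit1 by -0.63 and Ifih1, a sensor of viral RNA, by -0.43. Hypoxia and glycolysis genes had lower means in 16 of 18 members, among them Ndrg1 at -0.47, Slc2a1, a glucose transporter, at -0.37 and P4ha1 at -0.36. Collagen genes had higher means, Col1a1 by 1.28, Col1a2 by 1.17 and Col3a1 by 0.59.

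In the combination against IFNbeta limma gave 0 genes past the threshold, with the smallest adjusted p, that of Samd9l, at 0.0575, and 5147 at an unadjusted p under 0.05 (2352 higher, 2795 lower). Trended and robust moderation also gave 0, median centring and leaving out the lowest 25% of genes gave 1 each, and array weights gave 1730. Leaving out IFNbeta replicate 3, the array with the skin transcripts and the highest interferon score, gave 2351 genes (591 higher, 1760 lower), and leaving out p19Arf+IFNbeta replicate 2 gave 1. The 5 genes with the smallest unadjusted p did not pass, although in each all 5 arrays of the combination lay beyond all 5 of IFNbeta. They were Samd9l at -0.55 (SE 0.09), Cmpk2 at -0.81 (SE 0.17), Ngp, a neutrophil granule protein, at 0.44, Acpp, an acid phosphatase, at -0.69, and Cacna1g, a T-type calcium channel, at 0.57, the last 4 at an adjusted p of 0.150.

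By the directional fry test 0 lists passed in the combination against IFNbeta, with a smallest adjusted p of 0.0948, that of hypoxia and glycolysis. That list had a score difference of -0.19 (SE 0.05), 5 members adjusted over the list alone and p = 0.0423 with an estimated correlation (adjusted 0.759). For the type I interferon list the adjusted p was 0.162, with 0 members past over all genes and 11 adjusted over the list alone (p = 0.0947 with an estimated correlation, exact permutation p = 0.0238). ER stress genes differed by -0.19 (SE 0.07, 13 of 17 lower, adjusted p 0.162), with Herpud1, an ER-associated degradation protein, at -0.42, and the cell cycle list by -0.31 (SE 0.14, 28 of 31 lower, 0.267), or -0.19 without p19Arf+IFNbeta replicate 4. Under quantile normalization the hypoxia, ER stress and cell cycle differences were -0.09, -0.08 and -0.20, and with the array spread as a covariate the cell cycle difference was -0.05. Without p19Arf+IFNbeta replicate 2 the ER stress list passed at 0.0438 and the hypoxia list at 0.0273, within ranges over the arrays left out of 0.0438 to 0.310 and 0.0273 to 0.310. With an estimated correlation neither list passed with all arrays, at an adjusted p of 0.759 each, and that test was not run without this array. In either direction 3 lists passed, at an adjusted p of 0.0465 each: the type I interferon list, fibroblast and matrix genes (score difference 0.23, SE 0.11, 0.14 without p19Arf+IFNbeta replicate 1 and 0.36 without the 5 arrays of lowest spread, 14 of 18 higher, directional 0.267) and endothelial markers. Their adjusted p-values in camera with an estimated correlation, a test of 1 direction, were 0.759, 0.759 and 0.830. These values cannot decide a change in either direction. The endothelial score differed by -0.04 (directional 0.821) and by 0.02 with the array spread as a covariate, and Emcn by -0.52.

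The combination against p19Arf alone compared tumors given both vectors with tumors given p19Arf. A lower dose of the p19Arf vector in the combination cannot be told apart here from an effect of IFNbeta. Inflammatory genes had higher means in the combination: all 17 of 17 NF-kB and inflammatory cytokine genes, with Il1a at 1.32 and Il1b at 0.75. Ccl3 was at 11.72 ± 0.59 against 10.67 ± 0.36 and Cxcl3 at 8.72 ± 0.47 against 8.05 ± 0.23 (SD, n = 5 each), and Cxcl2 differed by 0.94 and Ccl4 by 0.45. The score of the type I interferon list differed by 0.11 (SE 0.13, 22 of 29 higher, fry adjusted p 0.629), or by 0.04 without p19Arf replicate 5, 0.06 without p19Arf replicate 4 and 0.18 without p19Arf replicate 2. No gene passed: limma gave 0, with a smallest adjusted p of 0.998 and 612 genes at an unadjusted p under 0.05, and array weights and trended, robust moderation also gave 0. The 5 genes with the smallest unadjusted p, at an adjusted p of 0.998, were Ccl3 at 1.05 (SE 0.21), Cxcl3 at 0.68 (SE 0.16), Ccrl2, a receptor-like protein that binds chemerin, at 0.72 (SE 0.18), the Y RNA gene Rny1 at -0.84 and Ctxn2 at -0.38. All 5 arrays lay beyond those of the other group in Ccrl2, Rny1 and Ctxn2, and 4 did in Ccl3 and Cxcl3.

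Among the lists in the combination against p19Arf 0 passed, with a smallest fry adjusted p of 0.319. The NF-kB list had a score difference of 0.30 (SE 0.11, adjusted p 0.319, p = 0.0117 with an estimated correlation, adjusted 0.130) and 2 members passing adjusted over the list alone, and the chemokine list one of 0.14 (SE 0.07, 14 of 24 higher, 0.372) and 4 such members. Endothelial markers differed by 0.13 (SE 0.05, 15 of 17 higher, 0.319), neutrophil markers by 0.22 (SE 0.11, 13 of 17 higher, 0.321), fibroblast and matrix genes by 0.23 (15 of 18 higher, 0.321), cytotoxic effectors by 0.28 (SE 0.13, 9 of 10 higher, 0.321) and T cell markers by 0.18 (15 of 16 higher, 0.322). Without p19Arf+IFNbeta replicate 1 the neutrophil and matrix differences were both 0.14, the cytotoxic difference 0.15 and the T cell difference 0.08.

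The direct comparison of the single vectors, IFNbeta against p19Arf, was the only contrast in which genes passed. Each of the 5 rose in IFNbeta relative to p19Arf tumors, and 0 of them belonged to a list fixed beforehand. Phf11d, a PHD finger protein, was higher by 1.05 (SE 0.16, adjusted p 0.0379), the interferon-induced Ifit3b by 1.14 (SE 0.19, 0.0421), Ms4a4d by 0.89 (SE 0.15, 0.0421), and the interferon-inducible PYHIN family members Ifi207 by 0.65 (SE 0.11, 0.0421) and Ifi213 by 1.05 (SE 0.19, 0.0459). In each gene all 5 IFNbeta arrays lay above all 5 p19Arf arrays. Phf11d was at 9.20 ± 0.43 in IFNbeta, 8.14 ± 0.31 in p19Arf and 8.46 in eGFP, and Ifi207 at 11.39 ± 0.21, 10.74 ± 0.24 and 11.16 ± 0.10 (SD, n = 5 each).

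**Figure D4:**
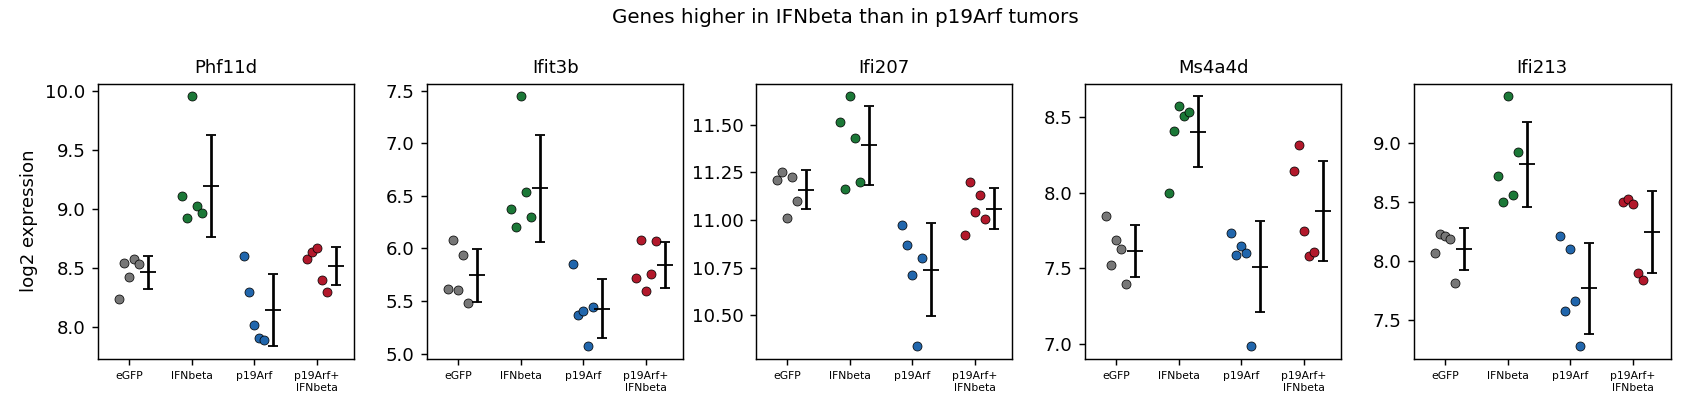
Log2 expression (vertical axes) of Phf11d, Ifit3b, Ifi207, Ms4a4d and Ifi213, the 5 genes that passed in IFNbeta against p19Arf, on each array by vector group; points are arrays and the bar beside them is the mean with its SD, n = 5. The differences between IFNbeta and p19Arf were 1.05, 1.14, 0.65, 0.89 and 1.05.

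The count of 5, all higher in IFNbeta, stood beside 4161 genes at an unadjusted p under 0.05 (1691 higher, 2470 lower). It became 0 under quantile normalization, with every probe set tested, with only these 2 groups fitted, with the array spread as a covariate and without the 5 arrays of lowest spread, 1 without the lowest 25% of genes, 1 with the replicate number as a block, and 4495 with array weights. With that block Ifi213 passed, while the adjusted p was 0.0506 for Phf11d and 0.111 for Ifit3b, Ms4a4d and Ifi207. It was 0 without IFNbeta replicate 4 or without p19Arf replicate 2, 3, 4 or 5, 1 without IFNbeta replicate 1, 2 without IFNbeta replicate 3, 3 without IFNbeta replicate 5 and 28 without p19Arf replicate 1. Over the alternatives the adjusted p of Phf11d ran from 2e-04 to 0.189 and that of Ifi213 from 0.00845 to 0.313.

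By the directional fry test 0 lists passed in IFNbeta against p19Arf, with a smallest adjusted p of 0.0707. That was the type I interferon list, with 29 of 29 members higher, 0 past over all genes, 22 adjusted over the list alone and a score difference of 0.46 (SE 0.13, 95% interval 0.19 to 0.73; p = 0.0253 with an estimated correlation). Usp18 differed by 0.79, Rsad2, viperin, by 0.81 and Ifih1 by 0.43. The list passed after median centring, at an adjusted p of 0.0363 within a range of 1.6e-17 to 0.360 over its alternatives. It also passed without IFNbeta replicate 4, p19Arf replicate 1 or p19Arf replicate 2, at adjusted p-values of 0.0486, 0.0354 and 0.0287, and 1, 3 and 1 lists passed in these fits. In either direction 2 lists passed, the type I interferon list (adjusted p = 0.0105) and endothelial markers (0.00337, directional 0.0831). In camera with an estimated correlation, a test of 1 direction, each had an adjusted p of 0.360. The endothelial score differed by 0.18 (SE 0.05, 14 of 17 higher; p = 0.0593 with an estimated correlation), with 2 members adjusted over the list alone: Emcn at 0.77 and Cdh5 at 0.57.

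Genes of killing and cell death also had higher means in IFNbeta than in p19Arf tumors without passing. All 10 of 10 cytotoxic effectors were higher, with a score difference of 0.39 (SE 0.13, fry adjusted p 0.0978, exact permutation p = 0.00794; p = 0.046 with an estimated correlation). Adjusted over the list alone 3 passed: Gzmb at 1.01, Gzmc at 0.80 and Prf1, the pore-forming perforin, at 0.40. Cell death effectors differed by 0.16 (SE 0.06, 16 of 18 higher, 0.0831), with Casp8 at 0.34 and Aim2, a sensor of cytosolic DNA, at 0.36 passing in that way. With the array spread as a covariate the cell death difference was 0.07, and under quantile normalization it was 0.10. ER stress genes differed by 0.19 (SE 0.07, 15 of 17 higher, 0.0978), or 0.10 with that covariate and 0.11 under quantile normalization, and NK cell markers by 0.14 (SE 0.07, 10 of 13 higher, 0.218). Among checkpoint and regulatory T cell genes 3 passed adjusted over the list alone, Il2ra at 0.53, Havcr2 at 0.46 and Tigit at 0.41 (score difference 0.11, 0.568; 0.07 without IFNbeta replicate 5, 0.06 without p19Arf replicate 5 and 0.19 without p19Arf replicate 2). The platelet genes Ppbp at 1.25 and Pf4 at 0.55 did so in the erythroid and platelet list, whose mean difference was 0.09 and whose median was -0.14 (0.919).

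The interaction asked whether the combination departed from the sum of the single vectors on the log2 scale. This reading assumes the same dose of each vector alone and in the combination, which the labels do not state. The type I interferon list had a value of -0.28 (SE 0.18, 95% interval -0.67 to 0.10), with 27 of 29 members below 0, and Samd9l stood at -0.41. The NF-kB list stood at 0.20, with 16 of 17 members above 0, and the p53 target list at -0.14 (SE 0.07, 20 of 27 below). The ER stress list stood at -0.15 (SE 0.09, 16 of 17 below). No list passed, with a smallest fry adjusted p of 0.679, and 0 members of these 4 lists passed over all genes or adjusted over the list alone; with an estimated correlation p was 0.0578 for type I interferon, 0.0547 for p53 targets and 0.0382 for ER stress. No gene passed: limma gave 0, all at an adjusted p of 1, with 260 at an unadjusted p under 0.05, and array weights and trended, robust moderation also gave 0. The 4 genes with the smallest unadjusted p were Aldh1b1, a mitochondrial aldehyde dehydrogenase, at 0.49, Fcrl5 at -0.71, Olfml1 at 0.41 and Samd9l at -0.41.

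Camera with its preset correlation called 16, 4, 10, 8, 16, 15 and 15 lists in the 7 contrasts, in the order in which they are described above, and with an estimated correlation 0 of these calls held. The contrasts against eGFP share the 5 eGFP arrays. Over the 19938 genes, which are not independent replicates, the differences of p19Arf and of the combination correlated at r = 0.80, against a median of 0.59 for unchanged groups simulated with shared controls, 16 of 100 of which were as high. The covariance was 0.0297 against 0.00939, with 5 of 100 as high, and r was 0.561 with the eGFP arrays split into 2 and 3. At an unadjusted p under 0.05, 156 genes were higher and 590 lower in both, with 0 in opposite directions; unchanged groups simulated with shared controls gave medians of 24 and 32, with as many in 15 and 3 of 100 simulations. For IFNbeta and the combination r was 0.10 (simulated 0.49, -0.02 with split controls) and the covariance 0.00278 against 0.00803, with 85 genes higher and 15 lower in both against simulated medians of 24 and 28.5 (as many in 19 and 69 of 100). For IFNbeta and p19Arf r was -0.06 (simulated 0.57, -0.20 with split controls) and the covariance -0.00125 against 0.00992, with 8 genes higher and 11 lower in both against simulated medians of 26 and 42 (as many in 76 and 77 of 100). No gene past the threshold was shared, since 0 passed in each contrast against eGFP.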

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

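The tests of the array with skin transcripts, of the small nucleolar RNA level, muscle, p19Arf and the share of tumour cells against the array spread, the splits with each array left out in turn and the regroupings over all contrasts were chosen only after the results were seen, as were the fits with the array spread and without the arrays of lowest spread.

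In 144 groups of 5 arrays, the highest or lowest array was set apart from the nearest other by more than 0.71 of the group's range in 17, where chance gives about 1 in 20, or 7.2. The array of IFNbeta replicate 3 accounted for 7 of them. Its skin epidermis score was 8.69 (others 6.51 to 6.64), its cell cycle score 9.71 (10.1 to 10.2), its dendritic cell score 7.80 (7.98 to 8.02), its Ifnb1 level 6.65 (6.03 to 6.20), its Ifit3b level 7.45 (6.20 to 6.54) and its Phf11d level 9.96 (8.92 to 9.11). Its spread of 2.04 was also apart from the 2.12 to 2.15 of its group.

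Other IFNbeta arrays that stood apart were replicate 5 in cytotoxic effectors at 8.36 (others 7.94 to 8.04) and replicate 1 in mast cell and eosinophil markers at 7.31 (7.06 to 7.12). In p19Arf, replicate 3 had a B and plasma cell score of 7.97 (6.65 to 6.95) and a T cell score of 7.75 (7.54 to 7.60), replicate 5 an MHC class I score of 10.5 (10.7 on the others) and an Ms4a4d level of 6.99 (7.59 to 7.73). P19Arf replicate 2 had a cytotoxic effector score of 7.53 (7.70 to 7.71) and replicate 4 an endothelial score of 8.01 (8.17 to 8.23). In eGFP, replicate 1 had a checkpoint and regulatory T cell score of 7.98 (7.65 to 7.74) and replicate 5 a skin epidermis score of 7.29 (6.63 to 6.80).

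The type I interferon list was higher in IFNbeta than in eGFP and lower in the combination than in IFNbeta, neither past the directional list test. With the array spread as a covariate the differences were 0.40 (SE 0.13) and -0.355 (SE 0.148), against 0.40 and -0.34 without it, which argues against the spread as the whole cause of either. Without IFNbeta replicate 3, the array with skin transcripts, the first was 0.279 (SE 0.105), so that array is not its whole source, although it may account for part. The second was -0.22 (SE 0.105) with an exact permutation p of 0.0556, so how far it rests on that array stays open. An effect of the vectors, which the design names, stays open for both and was not tested separately. For the second, a lower dose of the IFNbeta vector in the combination stays open as well.

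The array spread ran from 1.99 to 2.15, and among arrays without p19Arf in the vector it averaged 2.11 against 2.06 with it (n = 10 each, permutation p = 0.0164). It fell with the small nucleolar RNA level (Pearson r = -0.762, permutation p = 0.00016), and also within groups (r = -0.691 for deviations from the group means), so the vector is not the whole source of that relation, and RNA quality or the share of small RNA is a candidate cause beside an effect of p19Arf. Against a lower share of tumour cells, 7 of 9 host cell lists had a higher r with the spread than the median of 1000 random lists of matched level, but 0 did so past the threshold (NK cell markers most, r = 0.378, with 15 random lists as high, adjusted 0.144; 6 and 0.0629 in a second draw), so it stays open. Skeletal muscle gave r = -0.036 (permutation p = 0.879, Spearman -0.045, permutation p = 0.852), with a 95% interval of -0.471 to 0.413 and 0.069 for deviations from the group means, which argues against muscle as the main cause. The cell cycle list followed the spread at r = 0.938, but 802 of 1000 random lists of matched level did so at least as closely, so that relation is one of expression level.

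Without IFNbeta replicate 3, limma called 2351 genes between the combination and IFNbeta, where it called 0 with all arrays, and array weights raised the counts of several contrasts. With the spread as a covariate 0 of the 2351 were called, and their median size fell from 0.51 (SE 0.144) to 0.20 (SE 0.121), a median ratio of 0.38, so the calls ended because the differences shrank, and the spread is a candidate explanation. That array was singled out for its count, so 100 splits of the 10 arrays were each refitted without each array in turn: 6 gave as many genes in the fit with the most (5 in a second draw), the highest other 7735, so chance could not be excluded. Of 100 regroupings of the 20 arrays 9 gave as many genes with array weights as the 4495 of IFNbeta against p19Arf, the highest 9557 (the weights did not converge in 1 of the 99 others, which was not among these), so weights fitted to the arrays at hand may account for that count. An effect of adding p19Arf to IFNbeta stays open and was not tested separately.

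Other splits of the same arrays were counted for each contrast, 100 of 126 possible splits into 5 and 5. For genes at an unadjusted p under 0.05, chance could not be excluded in any contrast: as many genes as the real 557, 1445, 3513, 5147, 612 and 4161 came in 34, 23, 7, 5, 55 and 6 of the 100, the real split included, and the highest of the others gave 5026, 5437, 6655, 8666, 7066 and 8529. These are IFNbeta, p19Arf and the combination against eGFP, the combination against IFNbeta and against p19Arf, and IFNbeta against p19Arf. For the interaction, 71 of 100 regroupings of the 20 arrays gave as many as 260, with up to 10652. For the 5 genes past the threshold in IFNbeta against p19Arf, 2 of 100 splits gave as many, the real one included, with the highest other at 4296. As many calls were thus uncommon among the splits of this contrast taken alone. Over all 7 contrasts, 9 of 100 regroupings of the 20 arrays gave 5 genes or more in the contrast with the most (highest other 6939) and 4 in a second draw (8542), so chance could not be excluded once the choice among contrasts is counted. For lists past in either direction, 3 of 100 splits gave as many as the 6 lists of the combination against eGFP (highest other 15), 4 as many as the 3 of the combination against IFNbeta (14) and 3 as many as the 2 of IFNbeta against p19Arf (13). These contrasts were picked for their calls by a test added after the results were seen, and over all 7 contrasts 14 of 100 regroupings gave 6 lists or more in the contrast with the most (highest other 16) and 6 in a second draw (17), so chance could not be excluded. Counts close to 5 of 100 depend on which splits were drawn. Splits or regroupings that call as many as 4296 or 8542 genes may reflect a structure of the samples other than the vector groups. The array spread is a candidate, since it went with the first principal component, which held 46.4% of the variance. The arrays of lowest and highest spread (1.99 and 2.15) stood at opposite ends of that component, at -45.9 and 31.2. All 5 arrays of lowest spread lay at -17.0 or below, and the 5 of highest spread at 20 or above. Whether those splits or regroupings followed the spread was not tested.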

How the results depend on the processing

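The array spread as a covariate, leaving out the 5 arrays of lowest spread and the fry test in either direction were chosen after the results were seen; the other alternatives were fixed beforehand. Over all alternatives and left-out arrays, 794 values of the named genes and 504 of the named lists kept their direction and their side of the threshold. Most of these had not passed and again did not, since 5 of 41 named gene results and 0 of the lists passed in the text. Of the named genes, 29 values passed that had not and 67 no longer passed, and 47 list values passed that had not. All 67 were of the 5 genes that passed in IFNbeta against p19Arf. Each of these genes passed in 4 or 5 of 10 or 11 alternatives, and in 2 to 4 of 10 fits without 1 array. The table has no background signal, so what is limited by signal over background could not be examined. Where nothing else is said, the cause of a change was not tested.

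Counts of genes past the threshold moved with array weights to 5 in IFNbeta against eGFP, 166 in the combination against eGFP, 1730 in the combination against IFNbeta and 4495 in IFNbeta against p19Arf, where the weights of the real groups converged. Without the 5 arrays of lowest spread they were 1, 3 and 0 in IFNbeta against eGFP, the combination against eGFP and IFNbeta against p19Arf. The combination against IFNbeta gave 1 gene after median centring and 1 without the lowest 25% of genes, where fewer genes were tested. IFNbeta against p19Arf, 5 in the text, gave 0 under quantile normalization, with every probe set, with the array spread as a covariate and with only the 2 groups fitted, where fewer arrays set the variance, and 1 without the lowest 25%. Leaving out each array in turn gave 0 to 84 in the combination against eGFP (84 without eGFP replicate 1), 0 to 2351 in the combination against IFNbeta (2351 without IFNbeta replicate 3, 1 without p19Arf+IFNbeta replicate 2) and 0 to 28 in IFNbeta against p19Arf. In the last, 28 was without p19Arf replicate 1, 0 without IFNbeta replicate 4 or p19Arf replicates 2 to 5, 1, 2 and 3 without IFNbeta replicates 1, 3 and 5, and 5 only without IFNbeta replicate 2. Without IFNbeta replicate 2 Ms4a4d did not pass (limma adjusted p 0.0677), so those 5 were not the same 5 genes.

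The numbers of lists past the threshold, 0 in each contrast by the directional test, were 16, 4, 10, 8, 16, 15 and 15 by camera with its preset correlation in the order of the text. In either direction they were 6 in the combination against eGFP, 3 in the combination against IFNbeta and 2 in IFNbeta against p19Arf. How these 3 counts depend on the other settings or on single arrays was not examined. Array weights gave 1 list in IFNbeta against eGFP and 5 in IFNbeta against p19Arf, where median centring gave 1. Leaving out each array gave 0 to 2 lists in the combination against IFNbeta (2 without p19Arf+IFNbeta replicate 2) and 0 to 3 in IFNbeta against p19Arf (1, 3 and 1 without IFNbeta replicate 4, p19Arf replicate 1 and p19Arf replicate 2).

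Under quantile normalization or median centring, 3, 7, 4, 2, 2, 3 and 2 of the 28 list differences changed sign in the order of the text. Among them, p53 targets in p19Arf against eGFP were -0.005 after median centring, and in the combination against eGFP cell death effectors were 0.0238 and ER stress genes 0.0525 under quantile normalization, and hair follicle keratins -0.0184 and -0.0328 in these settings. Of the values followed through all alternatives, these changed sign. The type I interferon list in p19Arf against eGFP was 8e-04 under quantile normalization and ran from -0.124 to 0.0182 over the arrays left out (0.0182 without p19Arf replicate 5). The chemokine list in the combination against eGFP was 0.0407 under quantile normalization, 0.0048 with array weights, 0.0508 with the array spread as a covariate and 0.0291 without the 5 arrays of lowest spread, and ran from -0.041 to 0.0344 over the arrays left out (0.0075 without eGFP replicate 5, 0.0344 without p19Arf+IFNbeta replicate 5). The endothelial list in the combination against IFNbeta was 0.015 with the array spread as a covariate. Ifnb1 in IFNbeta against eGFP was -0.0017 with array weights and -0.0056 without the 5 arrays of lowest spread, and ran from -0.01 to 0.15 over the arrays left out (-0.01 without IFNbeta replicate 3). With the eGFP arrays split into 2 and 3, the correlation of differences was -0.20 for IFNbeta and p19Arf, -0.02 for IFNbeta and the combination and 0.561 for p19Arf and the combination; the split removes the shared controls and leaves fewer control arrays.

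With the replicate number as a block, IFNbeta against p19Arf gave 1 gene (smallest adjusted p 0.0450, within a range of 2e-04 to 0.176 over the alternatives) and no other count of genes or lists moved. Over 30 pairs of arrays with the same number the correlation of deviations from the group means ran from -0.624 to 0.657 and was over 0.1 in 11, and 3 of 20 arrays correlated best with an array of their own number, so the number is not shown to pair the arrays.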

Other observations

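The tests of the clock genes and of p19Arf and IFNbeta over 10 arrays each, and the count of list members without IFNbeta replicate 3, were chosen only after the results were seen. The relation of Ifnb1 to the interferon list was chosen after the values of that array had been seen.

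Cpa3 and Mcpt4, genes of mast cell granules, had lower means in both groups whose vector carried p19Arf, but the mast cell and eosinophil list did not pass: its score differed from eGFP by -0.08 in p19Arf (median member difference 0.01, fry adjusted p 0.999) and by -0.12 in the combination (0.238), where Hdc stood at 0.67. Cpa3 was at 8.95 ± 0.38 in eGFP and 8.66 ± 0.63 in IFNbeta, against 7.88 ± 0.41 in p19Arf and 7.98 ± 0.44 in the combination (SD, n = 5 each). Mcpt4, a mast cell chymase, was at 8.28 ± 0.22 and 8.33 ± 0.25 against 7.92 ± 0.30 and 7.83 ± 0.35. Ngp, a neutrophil granule gene, had its higher means in the same groups, 6.03 ± 0.12 and 6.20 ± 0.17 against 5.82 ± 0.06 in eGFP and 5.76 ± 0.09 in IFNbeta. These 3 genes were picked after their values were seen.

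With the 10 arrays of the p19Arf groups set against the other 10, limma gave 0 genes past the threshold, with a smallest adjusted p of 0.0610. At an unadjusted p under 0.05 there were 6535 genes, where 5% of the genes is about 997. Genes move together, and random splits of arrays into 5 and 5 gave up to 8666. No regroupings were counted for 10 against 10, so this count cannot be set against chance. The array spread also differed between these 10 and 10 arrays (2.06 against 2.11, permutation p = 0.0164). The spread, an effect of p19Arf and chance therefore cannot be told apart in this count. Hypoxia and glycolysis had the smallest list adjusted p, 0.127. With the 10 arrays of the IFNbeta groups set against the other 10, it gave 0 genes, a smallest adjusted p of 0.417 and 981 genes unadjusted, and the type I interferon list had the smallest list adjusted p, 0.184.

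Without IFNbeta replicate 3, the 2351 genes called between the combination and IFNbeta, 11.8% of the 19938 tested (8.83% lower and 2.96% higher), held 15 of 31 cell cycle genes, all lower in the combination, 6 of 29 type I interferon genes, all lower, and 6 of 18 hypoxia and glycolysis genes, all lower. Of 18 fibroblast and matrix genes, 4 were called higher and 2 lower. Col1a1 differed by 1.58, the imprinted noncoding RNA gene Meg3 by 1.47 and Stc1 by -1.13, each at an adjusted p of 0.0377, but by the directional list test 0 lists passed (cell cycle 0.0923, hypoxia 0.0783). With the array spread as a covariate 0 of the 2351 calls remained, and the cell cycle list followed the spread at r = 0.938.

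Dbp was among the genes with the smallest p in IFNbeta and in the combination against eGFP, and a hypothesis was that tumors of the groups were taken at different times of day. A phase score, the mean of 9 clock output genes minus that of 4 genes of the opposite phase, was -0.26 ± 0.10 in eGFP and -0.56 ± 0.04 in IFNbeta (SD, n = 5 each), a difference of -0.31 with an exact permutation p of 0.00794, the smallest possible. In p19Arf it was -0.40 (exact permutation p = 0.0714) and in the combination -0.50 (exact permutation p = 0.0238). Both arms moved apart, by -0.16 and 0.15, but Ciart, an output gene, went the other way at 0.31. The genes of the score were listed after several of them had been seen, and an effect of the vectors on clock genes stays open, so the time of day may contribute and is not shown.

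IFNbeta replicate 3 was highest in both Ifnb1 and the interferon list, and a hypothesis was that more Ifnb1 transcript goes with a higher list score. Over 20 arrays Pearson r was 0.472 (permutation p = 0.0428) and Spearman rho 0.253 (permutation p = 0.28). Without the 2 arrays farthest from the median of Ifnb1 r was 0.231, and for deviations from the group means it was 0.35. The relation was weaker without those 2 arrays but kept its sign, so how far it rests on them stays open. It was the only relation computed for this question.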
